A study of Homo sapiens with 2 samples.

How the data were processed

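Barcoded WTC-11 cells, treated with 1, 3, 5 or 7 µM CHIR together with BSA at 500 µg/mL and AA at 213 µg/mL, were pooled on day 2 into 1 sample, from which a gene expression library and a barcode library were made with a droplet 3′ kit, per the labels' protocols. The deposited values are counts of UMIs per gene and cell barcode, made by the authors with Cell Ranger, per the submitters' processing notes, which also name Seurat and the builds GRCh38 and hg38. The headers of the matrix files name Cell Ranger software version 3.1.0. The annotation release, the way cell barcodes were called and the filters used before deposit are not given in the sources used here. Both matrices hold whole numbers, with 33538 genes in the gene expression library and the same genes plus 20 line barcodes in the barcode library.

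The libraries were joined by cell barcode. Of 10377 cell barcodes in the barcode library, 10028 were in the gene expression library too, with a median of 159 line barcode UMIs (5th percentile 83). The following choices were made before the data were examined, unless said otherwise. A cell was kept with at least 1000 detected genes, at most 15% mitochondrial UMIs, no doublet call from Scrublet (run in scanpy, expected rate 0.1, seed 0) and no second line barcode. It was assigned to a line barcode with at least 2 UMIs and at least 80% of the cell's line barcode UMIs, and counted as a doublet between populations with at least 2 UMIs of each of 2 barcodes and none at 80%. Of 25691 cell barcodes, 3898 were below the gene minimum, 5798 above the mitochondrial maximum and 19066 passed both. Scrublet called 2420 of these doublets (12.7%), at an automatic threshold of 0.223. It called 42.0% of the 2229 cells with 2 line barcodes and 12.4% of cells with 1. The 1292 cells with 2 line barcodes that it did not call were left out as well. Whether these are doublets or single cells with stray barcode UMIs was not tested. Doublets within a population, or with a cell that carries no line barcode, can remain. In assigned cells the own barcode made up a median of 95.3%, 89.4%, 87.3% and 86.0% of line barcode UMIs in bcbg_07, bcbg_09, bcbg_12 and bcbg_16.

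Kept cells were scaled to 10000 counts per cell, log transformed after adding 1, reduced to 2000 highly variable genes and 30 principal components, and clustered with the Leiden algorithm (15 neighbours, resolution 0.5, seed 0). A cluster got a name from 12 fixed lists of 12 cell type markers. The name was that of the list with most members among the 30 genes of highest fold over all other cells, counting genes with a UMI in at least 10% of the cluster's cells and at least 1.5-fold higher CPM, with at least 3 detected markers. Ties and contradicting genes left a cluster unnamed. Contradicting genes were counted as more markers of another list past the same bounds, a way of counting set after the clusters were seen. Names are rebuilt from markers and may differ from those of the study.

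UMI counts were summed per population, or per cluster, and divided by the sum over all genes to give CPM, with exact Poisson 95% intervals. Shares of cells have exact Clopper-Pearson 95% intervals, and a count of 0 is given with the share that 3 cells would make. Ratios of 2 sums have exact conditional binomial intervals. The 12 cell type lists and 18 pathway lists were scored by the median over members of the log2 ratio of CPM plus a pseudocount of 1, for populations against the median population and for clusters against all other kept cells. The median's percentile among 10000 random lists, matched on mean expression in 20 bins, describes it. Genes with fewer than 100 UMIs in the compared cells could not be drawn. Some genes stand in 2 lists, such as FOXA2, CHRD and MSX1. Shares of cells with a UMI and cell cycle phases (scanpy, from the S phase and the G2 and M phase lists) were computed after each cell was thinned to 7000 UMIs, the 10th percentile of kept cells rounded down to a multiple of 500.

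The genes named in the text follow a fixed rule. Not every gene that meets it is printed, and some are left out because they were withheld. From each list these are the 2 to 4 members with most UMIs and members with a ratio of at least 2-fold and an interval that excludes 1.5-fold. For populations without a dose these are the 20 genes with the largest ratio of the highest to the lowest population's CPM, among genes with at least 100 CPM in the highest population. The top 10 genes by fold of each cluster only describe it. Genes of the barcode library were named after their values were seen. Gene identifiers and symbols are those of the files. Coordinates come from GENCODE release 29 on GRCh38, in which 33456 of 33538 gene identifiers (99.8%) were found.

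No test between groups was made. The names of the line barcodes state no dose, so the model planned for doses with replicate populations was not run, and correlations across populations were not computed because 4 populations are fewer than the 6 that were required. Alternative cell filters, assignment bounds, clustering settings, scalings and depths were tried. Scrublet's calls, the fixed seeds and the depth gap between cells with and without a line barcode can shift shares, and sums of counts weigh deep cells more.

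The calculations were tested on simulated Poisson counts, drawn from the library's mean expression at rounded totals near those of the populations. For 100 genes simulated at 2-fold, 94 intervals held the true ratio and 100 lay above 1.5-fold. At 4-fold the numbers were 97 and 100 of 100. Of 5067 genes simulated without a difference, 0 had an interval outside 1.5-fold and 95.2% of intervals held the true ratio. Because the counts were drawn as Poisson, such coverage was built in and checks only the calculation. These ratios used genes above a minimum of expression and the totals near bcbg_07 and bcbg_09. They say nothing about genes with few counts or about the smaller total of bcbg_16. Of 120 list values without a difference, 12 fell below percentile 2.5 or above 97.5, with medians no further than 0.04 from 0, with 1000 random lists each, so a percentile near 0 or 100 was read only beside the size of its median. A list simulated at 2-fold had a median of 0.98 and percentile 100.

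Tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, scanpy 1.11.5, leidenalg 0.10.2, igraph 0.11.9, umap-learn 0.5.12, scikit-learn 1.9.0 and matplotlib 3.10.9.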

Results

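The series follows human pluripotent cells that leave pluripotency under graded Wnt stimulation. Cells of WTC-11, a human induced pluripotent stem cell line, carried an internal barcode and were treated on day 0 with 1, 3, 5 or 7 µM CHIR, the Wnt-stimulating small molecule of the study. Cells of the 4 doses were harvested on day 2, pooled, sorted for single viable cells and profiled in 1 droplet run, from which 2 libraries were made. The gene expression library held 431125194 unique molecular identifiers (UMIs) in 25691 cell barcodes, with a median of 16026 UMIs and 3810 detected genes per cell barcode. The barcode library held 2056769 UMIs in 10377 cell barcodes, of which 1986704 came from the line barcodes. Each library is a single sample, so nothing here has a replicate, and 95% intervals (exact Poisson for CPM, exact Clopper-Pearson for shares) cover counting error only.

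Of 20 line barcodes, 4 carried nearly all barcode UMIs, and each of these marked 1 population. Line barcode bcbg_07 held 838784 barcode UMIs, bcbg_09 531503, bcbg_12 388500 and bcbg_16 227838, while the other 16 barcodes held 79 UMIs in all. Neither the labels nor the barcode names tie a line barcode to a CHIR dose, so the 4 populations have no dose here, no comparison between doses was made, and each population's value is given on its own. After filtering, 15354 cells remained (59.8% of cell barcodes), and 6520 of them were assigned to a population, namely 1720 to bcbg_07, 2271 to bcbg_09, 1684 to bcbg_12 and 845 to bcbg_16. In that order the populations summed to 45315475, 54476847, 40997254 and 19910339 UMIs, with medians of 25130, 22803, 23272 and 22035 UMIs per cell and of 9.14%, 7.67%, 9.03% and 8.41% mitochondrial UMIs. Values listed below for the 4 populations stand in the same order. Before filtering, cell barcodes present in the barcode library had a median of 25509 UMIs and those absent from it 8073.

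The kept cells fell into 11 clusters, which held paraxial mesoderm-like, cardiomyocyte-like and endothelial or blood progenitor-like cells beside 8 clusters left unnamed. Cluster 4 (1926 cells, 12.5% of kept cells) was paraxial mesoderm-like, with the presomitic genes DLL1, TBX6, RSPO3 and DLL3 among its leading genes. Cluster 5 (1892 cells, 12.3%) was cardiomyocyte-like, led by the sarcomere genes TNNI1, MYL7 and MYH6 together with the matrix gene LUM, and 9 mesenchymal markers passed the same bounds there as 9 cardiomyocyte markers. That name depends on the settings, since it covered only 573 cells (3.73% of kept cells) at a clustering resolution of 1.0 and no cluster when mitochondrial UMIs were limited to 10%. Cluster 10 (79 cells, 0.515%) was endothelial or blood progenitor-like, with CDH5 and PLVAP. Among the unnamed clusters, cluster 1 (2499 cells, 16.3%) was led by DKK4, SST and PRSS1 and passed the bounds for 9 primitive streak and 9 endoderm markers. Cluster 2 (2313 cells, 15.1%) had NANOG and GDF3 among its leading genes and passed the bounds for 6 pluripotency and 7 primitive streak markers. Cluster 6 (1783 cells, 11.6%) had CUZD1, IDO1 and FEZF1 among its leading genes and passed the bounds for 9 pluripotency markers. Cluster 3 (2007 cells, 13.1%) was led by CA3 and SPP1, cluster 7 (1335 cells, 8.69%) by FOXC2 and EBF2, cluster 8 (916 cells, 5.97%) by TTR, FGB and APOA1, cluster 9 (553 cells, 3.60%) by SCGB1A1 and SOX21, and cluster 11 (51 cells, 0.332%) by CBFA2T3 and FOXP2. Markers past the bounds included 7 of node or notochord in cluster 3, 9 of endoderm in cluster 8 and 8 of primitive streak in cluster 11. The leading genes and markers describe the clusters and are not results about them. Some cells without a name here earned 1 under other settings. At resolution 1.0 there were definitive endoderm-like clusters of 911 and 621 cells, a primitive streak-like cluster of 899 and a node or notochord-like cluster of 760, definitive endoderm-like clusters also appeared with at least 2000 detected genes and with at most 10% mitochondrial UMIs, and a node or notochord-like cluster with the latter.

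Nearly all cells with a line barcode lay in 4 of the 11 clusters. Clusters 1, 2, 4 and 6 held 99.6% of the assigned cells. The other 7 clusters, which include the cardiomyocyte-like cells and the cluster led by the liver genes TTR and APOA1, held 6833 cells, 44.5% of kept cells (43.7 to 45.3%), of which 26 were assigned. Their median depth was 10614 UMIs per cell against 22266 in clusters 1, 2, 4 and 6, where 76.2% of 8521 cells were assigned. Within these clusters the depth gap was smaller, with medians for cells present in and absent from the barcode library of 19984 and 17361 UMIs in cluster 1, 25517 and 20865 in cluster 2 and 23014 and 18716 in cluster 4, except in cluster 6, with 25108 and 5502, where 84 cells were absent.

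Each population took a different place among these clusters. Population bcbg_07 lay almost wholly in cluster 6, at 98.8% (98.1 to 99.2%) of its cells. Population bcbg_09 was divided between cluster 1 (48.2% (46.1 to 50.3%)) and cluster 2 (51.0% (49.0 to 53.1%)). Population bcbg_12 lay mostly in the paraxial mesoderm-like cluster 4, at 80.9% (79.0 to 82.8%), with 14.1% (12.5 to 15.9%) in cluster 2. Population bcbg_16 lay in cluster 1 (57.0% (53.6 to 60.4%)), cluster 2 (31.0% (27.9 to 34.2%)) and cluster 4 (11.8% (9.73 to 14.2%)). The paraxial mesoderm-like share was 0.528% (0.273 to 0.921%) in bcbg_09, and 0 of 1720 cells of bcbg_07 were in that cluster. For bcbg_07 the exact 95% interval reaches 0.214%, and 3 cells would make a share of 0.174%. Clusters were built from the same expression values as the gene levels below, so these shares restate them, and they cover only cells that the barcode library lists.

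**Figure D1:**
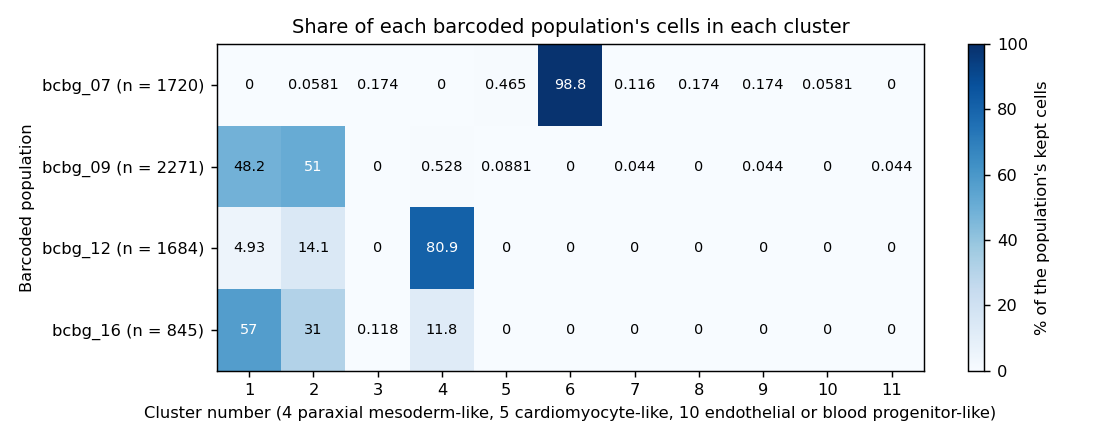
Share of each barcoded population's kept cells (vertical axis, with the number of cells) in each of the 11 clusters (horizontal axis), as percent in each square and by colour. Population bcbg_07 has 98.8% of its cells in cluster 6 and bcbg_12 has 80.9% in cluster 4, while bcbg_09 and bcbg_16 are spread over clusters 1 and 2.

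Germ layer markers separated bcbg_07 from the other populations and also the other populations from each other. The primitive streak list, genes of the embryonic structure through which mesoderm and endoderm form, was lowest in bcbg_07, where all 12 members were at least 2-fold below the median population. MIXL1, a homeobox gene of the streak, stood at 8.21, 466, 465 and 461 CPM. The streak genes NODAL and EOMES were highest in bcbg_09, with 4.59, 321, 101 and 263 CPM for NODAL and 5.27, 198, 63.5 and 136 CPM for EOMES, whereas TBXT (brachyury) was highest in bcbg_12, with 5.58, 51.5, 199.7 and 178 CPM. The list's median log2 ratio to the median population was -3.87, 0.48, -0.64 and 0.49.

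Pluripotency genes were highest on the whole in bcbg_07 and lowest in bcbg_12. The list medians were 0.67, 0.23, -0.62 and -0.21. SOX2, a core pluripotency factor that is also kept in neural fates, had the largest ratio of these genes, at 323, 63.6, 11.6 and 21.0 CPM. POU5F1, another core factor, differed less, at 1047, 1264, 749.6 and 1070.0 CPM, and L1TD1 stood at 348, 290.2, 119 and 208 CPM. NANOG ran against its list, with 8.12 CPM (7.31 to 8.99) in bcbg_07 and 39.8 CPM (38.1 to 41.5) in bcbg_09.

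Markers of paraxial mesoderm, the tissue that forms the somites, were highest in bcbg_12. The list medians were -2.44, -1.03, 2.18 and 0.61, and 8 of 12 members were at least 2-fold above the median population in bcbg_12. TBX6, a regulator of presomitic fate, stood at 2.56, 12.1, 119 and 37.8 CPM. The Notch ligand gene DLL3 stood at 12.3, 39.8, 378 and 131 CPM and CDX2, a posterior patterning factor, at 0.728, 0.955, 75.5 and 12.7 CPM. Other members of the list were highest elsewhere, such as FGF17 in bcbg_09, at 13.7, 950.2, 424 and 814 CPM. Cardiac and lateral mesoderm genes were also highest in bcbg_12, with medians of -1.01, -0.13, 0.71 and 0.05. In that list APLNR, a receptor gene of early mesoderm, stood at 4.37, 50.4, 223 and 129 CPM, and MESP1, a factor of cardiac mesoderm, at 1.43, 12.0, 39.4 and 23.5 CPM, whereas TMEM88 was highest in bcbg_07 with 47.0, 26.4, 6.88 and 16.5 CPM.

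Definitive endoderm genes were highest in bcbg_09, with list medians of -1.78, 0.82, -0.81 and 0.34. SOX17, a master regulator of endoderm, stood at 1.32, 108, 4.83 and 27.2 CPM, and HHEX at 1.85, 65.0, 13.1 and 40.5 CPM. CXCR4, a chemokine receptor gene of the list with more UMIs than HHEX, was instead highest in bcbg_12, at 4.68, 33.6, 85.0 and 34.8 CPM. FOXA2, shared by endoderm and node, was about level between bcbg_09 and bcbg_16, at 4.77, 166, 41.6 and 178 CPM. Node and notochord genes were highest in bcbg_16, where 6 of 12 members were at least 2-fold above the median population, with list medians of -1.24, 0.19, -0.22 and 1.14. FOXJ1, the regulator of motile cilia genes, stood at 7.48, 80.1, 35.6 and 211 CPM, and the cilium genes PIFO and TPPP3 stood at 18.9, 43.9, 45.3 and 129 CPM and at 1.08, 8.06, 7.88 and 71.7 CPM. Other members of the list did not follow. SHH was highest in bcbg_09, at 0.463, 5.53, 0.659 and 4.47 CPM, and SHISA3 was lowest in bcbg_16, at 1.92, 0.991, 1.39 and 0.502 CPM.

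For CDX1, SOX17 and FOXJ1 the populations kept their order in the share of cells with a UMI, after each cell was thinned to 7000 UMIs. Other genes did not keep it. FGF17, highest by CPM in bcbg_09, had a UMI in 7.76, 73.5, 79.5 and 83.4% of cells (23.8, 82.7, 93.2 and 90.8% unthinned). MIXL1, about level by CPM outside bcbg_07, had a UMI in 4.61, 72.0, 86.3 and 80.8% of cells (14.4, 86.3, 97.4 and 93.6% unthinned). CDX1 had a UMI in 0.934, 5.33, 71.1 and 27.6% of cells (3.08, 14.6, 93.8 and 54.3% unthinned) and SOX17 in 0.817, 20.6, 1.90 and 6.64% (2.56, 25.4, 3.56 and 10.7% unthinned). FOXJ1 had a UMI in 4.96, 34.0, 14.3 and 55.9% of cells (15.99, 56.4, 29.2 and 72.3% unthinned). Population bcbg_07, the deepest at a median of 25130 UMIs, had the lowest share for each of these genes, and how much of it is free RNA was not tested.

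**Figure D2:**
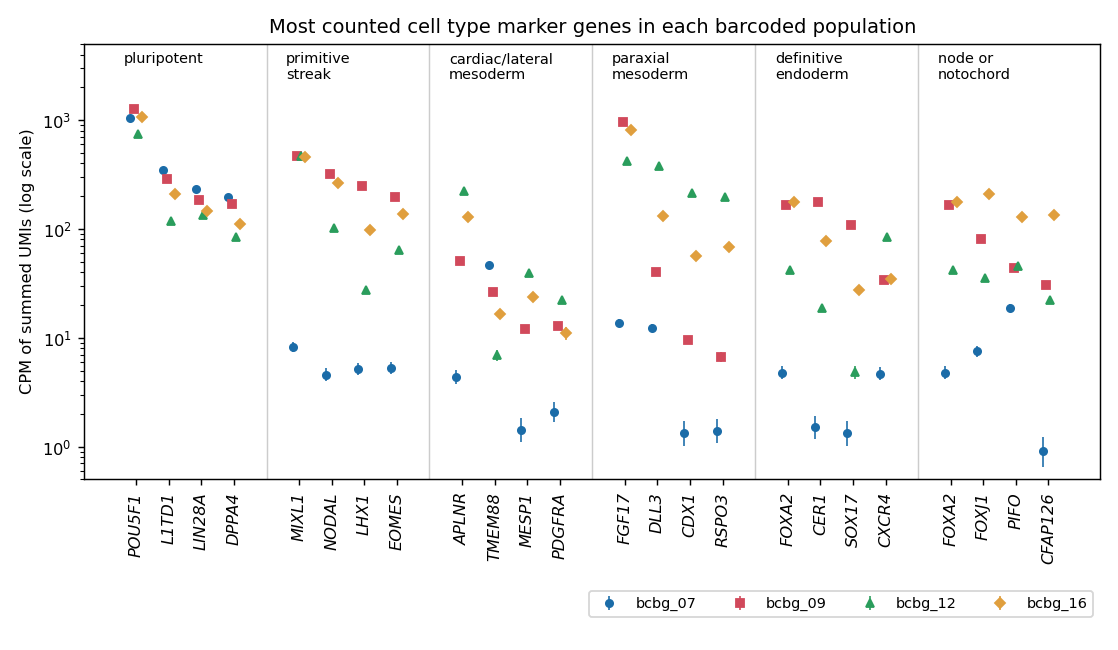
CPM of summed UMIs (vertical axis, log scale) of the most counted members of 6 cell type lists (horizontal axis) in each barcoded population, with exact 95% Poisson intervals that are mostly smaller than the symbols. MIXL1 is at 8.21 CPM in bcbg_07 and between 461 and 466 CPM in the other populations, whereas POU5F1 lies between 749.6 and 1264 CPM in all 4.

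For lists of tissues beyond the streak and its first derivatives the medians lay near 0 but say little. On the neural, amnion and endothelial lists most members lay near or below 1 CPM, where the pseudocount of 1 CPM holds ratios near 0. On the germ cell list this held for some members, while others, such as PDPN and SOX15, lay above 1 CPM in all 4 populations. The neural ectoderm list had medians of 0.05, 0.00, -0.01 and 0.00, the non-neural ectoderm or amnion list 0.03, 0.00, 0.00 and 0.00, and the endothelial or blood progenitor list 0.02, -0.04, 0.01 and 0.05. The primordial germ cell list had medians of 0.11, 0.07, -0.25 and 0.05, the cardiomyocyte list 0.17, 0.15, -0.21 and -0.01 and the mesenchymal or fibroblast list 0.09, 0.02, -0.03 and -0.01. Single members stood apart all the same, with 4 neural and 3 cardiomyocyte members at least 2-fold above the median population in bcbg_07. For cardiac genes a few cells can weigh on such sums. MYL7 stood at 27.0, 12.3, 12.9 and 8.94 CPM, but at 3449 CPM in the cardiomyocyte-like cluster 5. That cluster held 8 of the 1720 cells of bcbg_07, 2 of bcbg_09, 0 of bcbg_12 and 0 of bcbg_16. How much of the bcbg_07 values these cells supply was not tested. SOX3, HESX1 and LHX5, neural plate genes, were highest in bcbg_07, at 27.8, 0.881, 1.34 and 0.804 CPM for SOX3 and 19.6, 5.67, 2.44 and 4.12 CPM for HESX1. KRT7, a keratin gene on the amnion list, stood at 11.8, 0.606, 0.390 and 0.502 CPM, and EGFL7, the most counted endothelial member, differed little, at 73.2, 84.9, 69.4 and 84.5 CPM. PDPN on the germ cell list stood at 30.1, 10.0, 8.44 and 9.69 CPM, and the cardiac genes TNNI3 and NPPB at 42.4, 20.6, 16.5 and 38.5 CPM and at 24.2, 3.51, 1.32 and 1.71 CPM. LMO2, a haematopoietic cofactor, was highest in bcbg_12 at 1.43, 1.32, 23.0 and 1.96 CPM, and TAGLN, an actin-binding gene of smooth muscle, was highest in bcbg_07 at 668, 61.9, 83.9 and 58.9 CPM.

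The 20 genes with the widest span between the highest and the lowest population belonged mostly to Wnt feedback, posterior mesoderm, Nodal signalling and cilia. CDX1 (ENSG00000113722, chromosome 5, 150166795 to 150184558), a posterior patterning factor, had the widest span, from 1.32 CPM (1.01 to 1.70) in bcbg_07 to 215 CPM (210.5 to 219) in bcbg_12, a ratio of 162 (95% interval 126 to 213). CFAP126 (ENSG00000188931, chromosome 1, 161364731 to 161367874), a cilium gene, spanned from 0.905 CPM in bcbg_07 to 135 CPM in bcbg_16, a ratio of 149.7 (95% interval 110.0 to 209). CUZD1 (ENSG00000138161, chromosome 10, 122832149 to 122850793) was the only one of the 20 that was highest in bcbg_07, at 158, 1.06, 3.49 and 2.91 CPM. RSPO3 (ENSG00000146374, chromosome 6, 127118604 to 127197765), a secreted enhancer of Wnt signalling, stood at 1.39, 6.70, 198 and 67.7 CPM. The Wnt antagonist gene DKK1 (ENSG00000107984, chromosome 10, 52314296 to 52318042) stood at 18.2, 531, 1676 and 980.1 CPM and its relative DKK4 (ENSG00000104371, chromosome 8, 42374068 to 42377232) at 3.66, 397, 106 and 327 CPM. CER1 (ENSG00000147869, chromosome 9, 14719724 to 14722717), a secreted antagonist of Nodal, BMP and Wnt ligands, stood at 1.52, 177, 18.6 and 76.6 CPM. Coordinates are on GRCh38, from GENCODE release 29.

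Among the other genes of this set, bcbg_12 was highest for MSX1 (ratio 73.4), HES7 (68.3), a gene of the segmentation clock, and CNTFR (59.0). Population bcbg_09 was highest for SOX17 (81.7), NODAL (70.0), FGF17 (69.5), GSC (64.1), TRDN (61.8) and MIXL1 (56.7), though for MIXL1 the interval of bcbg_09 (460.0 to 471) overlapped those of bcbg_12 and bcbg_16. Population bcbg_16 was highest for SST (75.7), the somatostatin gene, and for PRSS1 (80.9) and PRSS2 (76.6), trypsinogen genes of near-identical sequence whose separate counts are uncertain. In 19 of the 20 the lowest population was bcbg_07. Free RNA limits such ratios. The leading genes of the 7 clusters with few assigned cells, 22 genes of at least 100 CPM there, reached in their highest population a median of 0.560% of the cluster's CPM (0.0414 to 3.93%). The population sums include the few assigned cells that lie in those clusters, such as 8 of bcbg_07 in cluster 5. These percentages therefore do not measure free RNA alone. The lowest values of the 20 genes with the widest span may be background.

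Wnt target genes were lowest in bcbg_07 and, for most members, highest in bcbg_12. The list medians were -1.22, -0.25, 1.02 and 0.26, with 8 of 16 members at least 2-fold above the median population in bcbg_12 and 10 at least 2-fold below it in bcbg_07. LEF1, a nuclear partner of beta-catenin, stood at 2.74, 7.62, 77.7 and 27.2 CPM, and NKD1, a feedback inhibitor, at 2.67, 10.1, 79.6 and 20.9 CPM. SP5, a direct Wnt target, was instead highest in bcbg_16, at 11.5, 436, 459 and 565 CPM, and DKK4 in bcbg_09. MYC, also on the list, was highest in bcbg_07, at 14.8, 12.2, 5.95 and 7.08 CPM.

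Nodal pathway genes followed another order, with medians of -0.95, 0.76, -0.62 and 0.43. LEFTY1, a feedback antagonist of Nodal, stood at 1.28, 49.2, 4.95 and 40.0 CPM. The coreceptor gene TDGF1 was highest in bcbg_07, at 499, 365, 95.6 and 248 CPM, and the transcriptional partner FOXH1 was lowest there, at 88.4, 287, 385 and 301 CPM. The FGF ERK target list was lower in bcbg_07 than in the other populations, with medians of -1.15, 0.06, -0.06 and 0.10, as in ETV4 at 16.9, 71.0, 55.6 and 64.8 CPM. BMP targets had medians of -0.14, 0.01, 0.48 and -0.07. Of these, ID3 stood at 345, 374, 510.3 and 317 CPM and MSX1 at 2.16, 15.9, 159 and 55.0 CPM, while ID1 was highest in bcbg_07, at 142, 32.3, 71.8 and 17.4 CPM. Notch and segmentation clock genes had medians of -0.20, -0.09, 0.11 and 0.16, with the clock gene HES7 at 2.27, 6.88, 155 and 53.8 CPM.

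Most anterior HOX and CDX genes were highest in bcbg_12. The list medians were -0.17, -0.16, 2.66 and 0.03, and 10 of 15 members were at least 2-fold above the median population in bcbg_12. HOXB1, an early gene of the HOXB cluster, stood at 0.199, 0.257, 40.4 and 2.26 CPM and HOXB2 at 1.02, 0.844, 38.5 and 2.91 CPM. Genes of the EMT and mesenchymal state were likewise highest in bcbg_12, with medians of -0.54, -0.28, 1.31 and 0.21. VIM, the intermediate filament gene of mesenchymal cells, stood at 223, 149, 742 and 222 CPM and SNAI1, a repressor of epithelial genes, at 4.41, 16.2, 68.8 and 31.9 CPM. CDH2 was lowest in bcbg_07, at 17.7, 193, 269.8 and 265 CPM. Epithelial genes had medians of 0.37, 0.09, -0.51 and 0.06. EPCAM followed its list only in part, being lowest in bcbg_12 but highest in bcbg_16, at 498, 665, 466 and 799 CPM.

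Metabolic genes set bcbg_07 apart from the other 3 populations. Glycolysis genes were lower there, with list medians of -0.82, 0.14, -0.06 and 0.06. LDHA, which makes lactate, stood at 335, 1308, 1094 and 1177 CPM and PGK1 at 305, 1041, 849 and 1132 CPM. The hypoxia list had medians of -1.22, 0.04, 0.00 and 0.10, but its members went both ways. BNIP3, a mitophagy gene, stood at 75.5, 872, 725 and 975 CPM and PDK1, which restrains entry of pyruvate into mitochondria, at 7.44, 90.8, 109 and 86.7 CPM, whereas ADM was highest in bcbg_07, at 55.3, 8.28, 4.22 and 4.67 CPM. Cholesterol synthesis genes had medians of -0.70, 0.03, 0.37 and -0.03, with FDPS, the most counted member, at 148, 167, 205 and 158 CPM. Oxidative phosphorylation genes differed little, with medians of 0.14, 0.00, 0.00 and -0.02, as in UQCRH at 1137, 1144, 1162 and 1137 CPM and COX4I1 at 993, 936, 928 and 913 CPM.

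The remaining lists concern stress and the cell cycle. S phase genes had medians of 0.54, -0.14, 0.11 and -0.24 and G2 and M phase genes 0.14, 0.02, -0.05 and -0.04. The unfolded protein response list had medians of -0.25, -0.06, 0.11 and 0.06, heat shock 0.11, -0.01, 0.01 and -0.08, p53 targets -0.28, -0.01, 0.11 and 0.01, and AP-1 and immediate early genes -0.17, -0.04, 0.15 and 0.00. Among their most counted members, the chaperone gene HSP90B1 stood at 399, 549.5, 567 and 594 CPM, HSPD1 at 1154, 1071, 875 and 895 CPM, the pro-apoptotic gene BAX at 167, 224, 243 and 231 CPM, JUND at 168, 249, 251 and 308 CPM and the chromatin gene HMGB2, of G2 and M phase, at 519.8, 341, 266 and 292 CPM. NASP, a histone chaperone gene of S phase, stood at 689.9, 373, 416 and 326 CPM. Of the 30 lists, 13 had a span of at least 1 on the log2 scale between the highest and the lowest population. Among 10000 random lists matched on expression, the Wnt target median lay at percentile 0 in bcbg_07 and 100 in bcbg_12. The hypoxia median lay at percentile 0 and the oxidative phosphorylation median at percentile 80.1 in bcbg_07. These percentiles describe this library and test nothing.

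**Figure D3:**
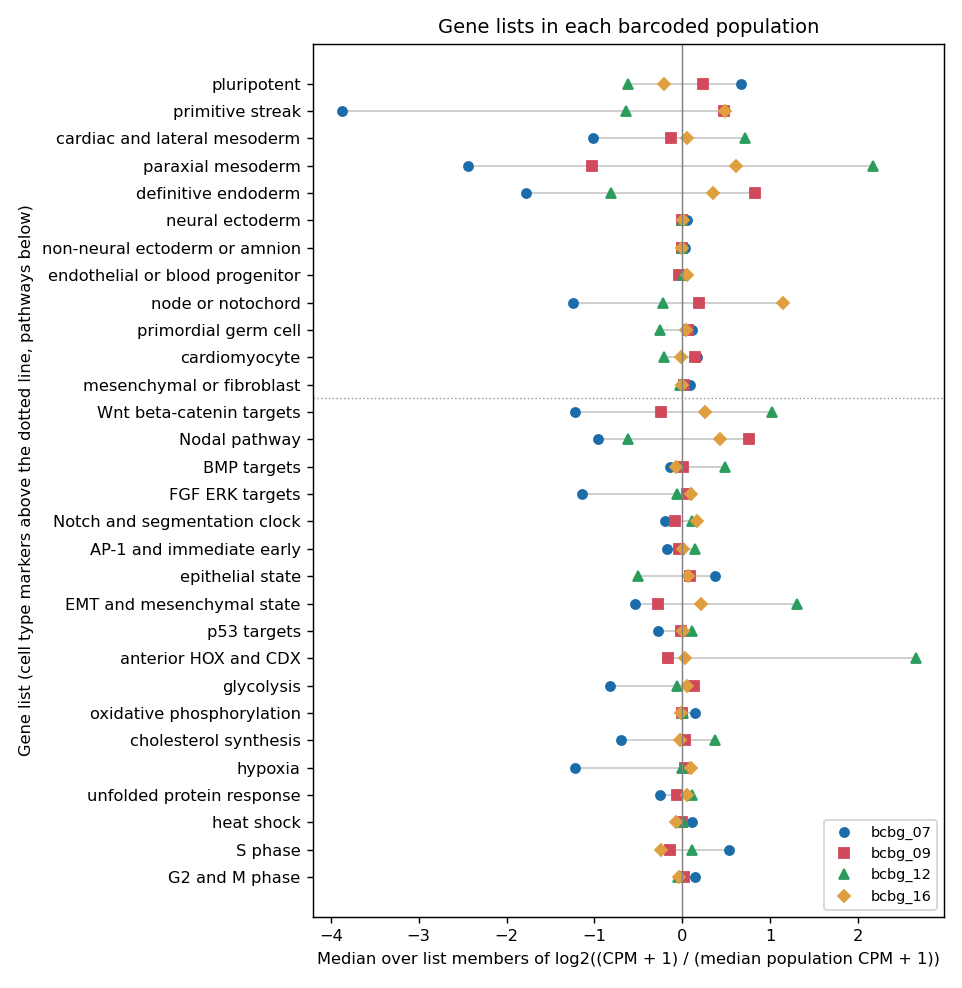
Median over list members of the log2 ratio of a population's CPM to the median population's CPM, with 1 added to both (horizontal axis), for 12 cell type and 18 pathway lists (vertical axis), with 1 symbol per population. The widest span is that of the paraxial mesoderm list, from -2.44 in bcbg_07 to 2.18 in bcbg_12, and in the anterior HOX and CDX list bcbg_12 stands alone at 2.66.

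Across clusters, each set against all other kept cells, BMP targets had the widest range of the pathway lists. They were highest in cluster 8, the cells led by TTR and APOA1, with a median log2 ratio of 2.44, and in the cardiomyocyte-like cluster 5, with 1.53. They were low in the 4 clusters that hold the assigned cells, at -2.18 in cluster 1, -2.54 in cluster 2, -1.57 in cluster 4 and -2.29 in cluster 6, but also in cluster 3, which has few assigned cells, at -1.38. Wnt targets were highest in the paraxial mesoderm-like cluster 4, at 1.08, and lowest in cluster 6, at -1.92. Nodal pathway genes were highest in cluster 2, at 0.59, and FGF ERK targets lowest in cluster 6, at -1.32, where the hypoxia list was lowest as well, at -1.57. EMT and mesenchymal genes were highest in cluster 5, at 1.18, and epithelial genes were lowest in cluster 10, at -2.43, and highest in cluster 9, at 0.76. Glycolysis genes were highest in cluster 2, at 0.72. Of 198 medians, for 18 lists in 11 clusters, 42 were at least 1 from 0 in either direction. The cluster depths differed, with median UMIs per cell from 7781 in cluster 3 to 24870 in cluster 6, and genes on these lists took part in the clustering. The other kept cells that served as reference included the 7 clusters with few assigned cells, whose origin is open.

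Cells called G1 were rarest in cluster 6. After thinning to 7000 UMIs per cell, the share of cells called G1 from the S phase and the G2 and M phase genes was 3.83% (2.98 to 4.85%) in cluster 6, 24.9% (22.9 to 26.9%) in the paraxial mesoderm-like cluster 4, 32.0% (30.1 to 34.0%) in cluster 2 and 55.1% (53.1 to 57.1%) in cluster 1. Unthinned, these shares were 6.17%, 32.0%, 38.1% and 62.7%. It was 48.8% (46.4 to 51.1%) in the cardiomyocyte-like cluster 5 (52.0% unthinned). It was highest among the clusters with few assigned cells, at 63.9% (61.1 to 66.7%) in cluster 7 (69.3% unthinned), 63.0% (50.9 to 74.0%) in cluster 10 (65.8% unthinned), 62.8% (60.1 to 65.5%) in cluster 3 (75.6% unthinned), 57.4% (52.96 to 61.7%) in cluster 9 (61.7% unthinned) and 55.8% (52.4 to 59.1%) in cluster 8 (59.8% unthinned). It was 29.03% (14.2 to 48.0%) in cluster 11 (43.1% unthinned). Unthinned, clusters 8 and 9 lay below cluster 1, and cluster 11 lay above cluster 2. By population the G1 share was 3.56% (2.73 to 4.55%) in bcbg_07, 34.2% (32.3 to 36.2%) in bcbg_09, 24.8% (22.7 to 26.9%) in bcbg_12 and 39.7% (36.4 to 43.1%) in bcbg_16 (5.52%, 39.8%, 31.3% and 47.3% unthinned). The S phase gene GMNN stood at 141, 67.2, 82.0 and 63.1 CPM and PCNA, the replication clamp, at 157, 87.3, 114 and 75.9 CPM. The thinning left out 1418 kept cells, 741 of them in cluster 3. Phase calls read free RNA too, which stays open here, and they do not by themselves measure cycling.

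**Figure D4:**
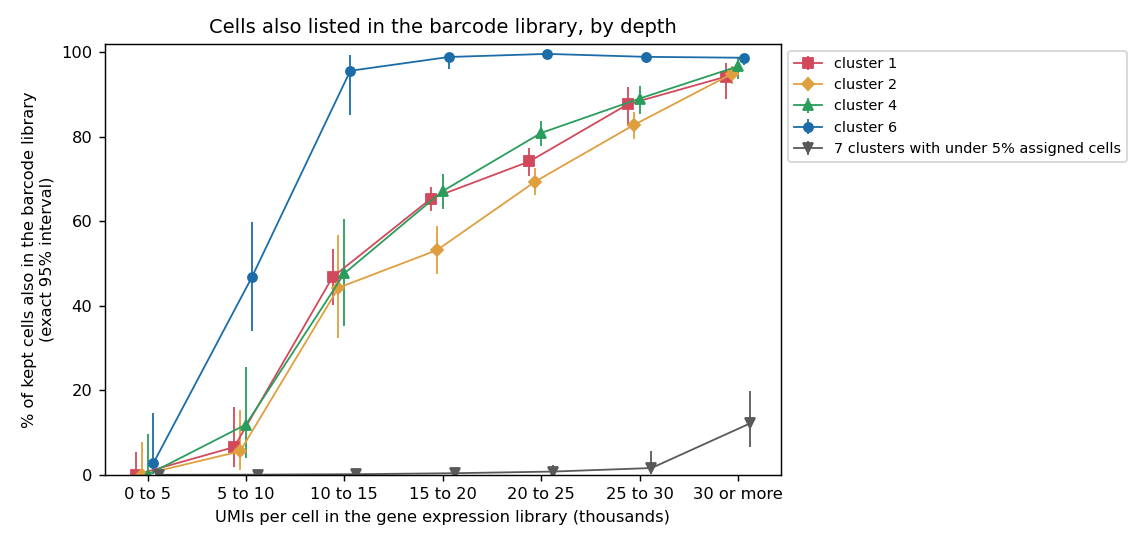
Share of kept cells that the barcode library lists (vertical axis, percent, with exact 95% intervals) by UMIs per cell in the gene expression library (horizontal axis, in units of 1000 UMIs), for clusters 1, 2, 4 and 6 and for the 7 clusters with few assigned cells together. At 20000 to 25000 UMIs, 99.7% of cluster 6 and 69.4% of cluster 2 were listed, against 0.763% of the 7 clusters.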

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

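The tests of the gene UMIs in the barcode library were chosen only after the result was seen. The barcode library, used above only for its line barcodes, also held 70065 UMIs of genes, 3.41% of its total and far above the limit of 3 counts, and 35054 of them lay in the 349 cell barcodes that the gene expression library does not list. Carry-over of molecules from the gene expression library may account for the gene UMIs in cell barcodes present in both libraries, where 104 of 105 genes with at least 50 UMIs (99.0%) held a share within 10 times of their share in the gene expression library. In cell barcodes found only in the barcode library this held for 65 of 99 genes (65.7%). Carry-over with the gene shares of the gene expression library therefore did not account for their gene UMIs. Carry-over of these cell barcodes' own molecules could not be tested, because the gene expression library does not list them. Molecules of cells outside this gene expression library were not tested as a source there and stay open, because the 14.9 times their share of the gene UMIs that these cell barcodes held only restates the observation. The genes furthest above their share were CHI3L1 (325 UMIs in the barcode library and 59 in the gene expression library) and the macrophage complement genes C1QA (187 and 34), C1QB (248 and 64) and C1QC (129 and 45), and no biological explanation was tested, because the design has no group that bears on them.

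The 16 line barcodes outside the 4 populations held 79 UMIs in all, above the limit of 3 counts, with at most 15 for any of them.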

How the results depend on the processing

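The counting of cluster names without contradicting genes, the pseudocount of 0.1 CPM, the bound of 60% for gene lists, the restriction to cells with at least 20000 UMIs and the keeping of cells with 2 line barcodes were tried after the data had been seen. No list median of at least 0.5 in size changed sign under any alternative tried. Kept cells numbered 11809 to 16837 over the alternatives. Bounds of 1 and 5 barcode UMIs assigned the same 6520 cells, so they test nothing further. A bound of 60% assigned 7598, unevenly, with 1743, 2473, 2113 and 1269 in bcbg_07, bcbg_09, bcbg_12 and bcbg_16. A bound of 95% left 1071, of which 961, 75, 31 and 4 were in the same order, so that only bcbg_07 kept 100 cells and no paraxial mesoderm-like share could be given for the others. At resolutions of 0.3 and 1.0 that share stayed within its interval in each population.

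The paraxial mesoderm-like share of kept cells was 12.5% and became 11.8% at resolution 1.0, 11.7% with at least 2000 genes and 11.6% with Scrublet doublets kept. The cardiomyocyte-like share was 12.3% and became 3.73%, 0% with at most 10% mitochondrial UMIs, where no cluster earned the name, and 13.8% with doublets kept. The share in clusters with few assigned cells was 44.5% and became 43.6% with at least 2000 genes, 46.9% with at most 10% mitochondrial UMIs and 41.6% with doublets kept. Without counting contradicting genes, cluster 2 became pluripotent-like, a share of 15.1%. Cluster 6 did not earn that name, although 9 pluripotency markers passed the bounds there against 6 in cluster 2. Unthinned G1 shares were 62.7, 38.1, 32.0 and 6.17% in clusters 1, 2, 4 and 6. Without thinning, the order was exchanged for clusters 1 and 8, 1 and 9, 2 and 11, 3 and 7, and 3 and 10. The cause of these shifts was not tested.

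Lists with a span of at least 1 between populations numbered 13 to 15, and cluster medians at least 1 from 0 numbered 41 to 46. Of 720 alternative list medians by population, from settings that can move them, 633 moved by no more than 0.1, as did 386 of 594 by cluster. Of the 20 genes with the widest span, 15 remained with totals that left out mitochondrial and ribosomal protein genes (CNTFR, GSC, MIXL1 and TRDN were among those lost) and 18 in cells of at least 20000 UMIs (CFAP126 and SOX17 were lost). Not run for want of doses were other forms of the dose model, namely DESeq2 in place of edgeR, no filter on low counts, a replicate block and leaving out each population, as well as the relations across populations.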

Other observations

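Of the tests below, only that in the band of 20000 to 25000 UMIs was chosen after the result was seen. Single members of the lists showed contrasts that the list medians hide. Among BMP targets, ID1 and ID4 were highest in bcbg_07, at 142, 32.3, 71.8 and 17.4 CPM for ID1 and 12.2, 2.70, 5.00 and 3.31 CPM for ID4, while BMP4 itself was highest in bcbg_12, at 2.98, 3.65, 13.7 and 2.26 CPM. Among p53 targets, PMAIP1, a pro-apoptotic gene, was highest in bcbg_07, at 438, 237, 99.9 and 159 CPM, and CDKN1A, a brake on the cell cycle, was highest in bcbg_12, at 0.397, 0.734, 5.78 and 2.56 CPM. EGLN3 joined ADM among hypoxia genes with their highest value in bcbg_07, at 18.2, 4.09, 4.05 and 2.46 CPM. The immediate early gene IER3 was lowest in bcbg_07, at 30.03, 206, 233 and 194 CPM. Among neural genes, SIX3 ran against SOX3, being highest in bcbg_09, at 4.35, 35.3, 1.59 and 15.9 CPM. HSP90AA1 was highest in bcbg_07, at 2070.2, 1008, 1188 and 999 CPM.

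In expression over genes with a mean of at least 10 CPM, bcbg_07 stood furthest from the others. Spearman's rho across these 7504 genes, which are not independent replicates, was 0.968 between bcbg_09 and bcbg_16, 0.940 between bcbg_12 and bcbg_16, and 0.932 between bcbg_09 and bcbg_12. With bcbg_07 it was 0.878 for bcbg_09, 0.842 for bcbg_12 and 0.829 for bcbg_16. The populations also differed in line barcode level, with medians of 11.9, 6.03, 5.11 and 4.97 own barcode UMIs per 1000 UMIs.

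The 7 clusters with almost no line barcodes held 44.5% of kept cells. Lower depth did not account for this, because among cells with at least 20000 UMIs the barcode library listed 2.88% of 625 cells in these clusters and 86.3% of 5590 in the others. A low level of the line barcode in these cells and cells from outside the barcoded populations cannot be told apart here. MYL7 had a UMI in 97.1% of cells of cluster 5 and TTR in 92.7% of cells of cluster 8, while the labels name only cells of day 2. Whether these clusters are a product of the 4 doses was not tested, and they are not read as such here. The 26 listed cells, fewer than the 30 set as needed, had a median of 6.42 barcode UMIs per 1000 UMIs against 7.22 elsewhere. The 18 listed cells among the deep ones are too many for the bound set for outside cells and too few for the opposite bound, and 13 of them had at least 30000 UMIs, a depth at which doublets may add a barcode, while no biological explanation was tested.

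The share of cells with a population call differed between clusters 1, 2, 4 and 6, by 28.9 percentage points from the lowest to the highest. The test of depth set beforehand decided nothing, since the gap of 19.4 points among cells with at least 20000 UMIs lay between its bounds of 10 and 20, but at nearly equal depth, in the band of 20000 to 25000 UMIs chosen afterwards, the gap was 30.2 points, which depth alone would not leave. Fewer line barcode transcripts per cell may contribute to the gap between cluster 6 and the others. The barcode levels below come from listed cells only, so they cannot show the level in unlisted cells. They decide nothing about the gap among clusters 1, 2 and 4. At 10000 to 20000 UMIs cluster 6, with 12.5 barcode UMIs per 1000 UMIs, had 98.3% of cells listed, 33.3 points above the highest of the other clusters, where the share was 62.1% in cluster 1 with 6.71, 51.6% in cluster 2 with 6.13 and 65% in cluster 4 with 5.98 barcode UMIs per 1000 UMIs, so that cluster 4, with the fewest, had the highest share of these. Cells counted as doublets between populations were listed too, but were left out before these shares were taken. With the bound of 60% in place of 80%, assigned cells rose from 1720, 2271, 1684 and 845 to 1743, 2473, 2113 and 1269 in bcbg_07, bcbg_09, bcbg_12 and bcbg_16. How far this filter adds to the gap was not tested. The populations' shares of assigned cells therefore need not equal their shares in the pool, and no biological explanation was tested.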
